A study of Mus musculus with 3 samples.

How the data were processed

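The deposited files hold whole-number counts per gene for 3 libraries of cultured mouse cortical neurons, with 54232 Ensembl gene identifiers in each and no entry that names no gene. Per the labels' protocols, total RNA was extracted with a column kit and made into libraries with a TruSeq Total RNA kit, whereas the molecule field of the labels reads polyA RNA. This conflict was left open. It bears on RNAs without a poly(A) tail, of which 4 of 20 replication-dependent histone genes and 1 of 14 listed small RNAs passed the expression filter. Per the submitters' processing notes, the tools used were cutadapt 4.2, STAR 2.7.5, HTSeq 2.0.2 and DESeq2 1.14.1, with the mm10 build. Their order, the annotation release, the strand setting and any filter are not given in the sources used here. The values are not normalised.

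Without a known strand setting, reads of overlapping genes and of antisense partners cannot be told apart. Genes with over 10% of their exonic bases shared with another gene were therefore marked as uncertain. Gene symbols, classes and coordinates came from GENCODE M21 (GRCm38), which matched 54079 of the 54232 identifiers. The other 153 held at most 0.0126% of the counts of a library.

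Groups came from the sample titles and library names, and each group has 1 library. With no replicates no statistical test between groups was made and no p-value is given. Library sizes were scaled with trimmed-mean (TMM) factors from edgeR 4.0.16 under R 4.3.3, which were 1.00, 0.990 and 1.01 for IKVAV PA, IKVAV PA + PEDOT-S and the PDL control. Genes were kept with at least 1 CPM in at least 1 of the 3 libraries, which left 13884. For each gene and pair of libraries, the ratio of scaled counts was given a 95% counting interval from the exact (Clopper-Pearson) binomial interval of the count in the first library given the sum of both. A gene counted as higher or lower when the bound nearest to no difference lay beyond 1.5-fold. Such intervals cover counting error only, since reads without molecular identifiers are not independent molecules, and they say nothing of differences between cultures.

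For 45 gene lists, the median over measured members of the log2 ratio (prior count 2) was set beside 10000 random lists of the same size matched on mean expression in 20 bins. The percentile of the median among these describes the libraries and is not a test. Lists with at least 3 measured members were used, 43 of the 45 in each of 3 comparisons. A list was said to lie outside the random lists below the 2.5 or above the 97.5 percentile. If genes varied independently of each other, about 1.07 of 43 lists would do so by chance on each side. In IKVAV PA against PDL 23 lay below and 3 above, in IKVAV PA + PEDOT-S against PDL 16 and 7, and between the scaffolds 8 and 15. Lists overlap in members, so these counts are not independent. Members of a list can also vary together between any cultures, which the random lists do not copy. The value of 1.07 therefore cannot show how far these counts go beyond chance.

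The groups, the comparisons, the size rule, the filter, the gene lists and the genes to be named were fixed before the data were examined. The named genes are the 10 highest and 10 lowest per comparison by the bound nearest to no difference (leaving out numbered gene models, pseudogenes, mitochondrial and antisense genes), up to 4 members per described list, up to 6 genes per direction that differ one way between IKVAV PA and PDL and the other way between the scaffolds, and 13 genes chosen in advance. Genes named outside this rule are said to be so. Some genes that the rule names are not reported here.

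The procedure was tested on simulated data with 13884 genes, in which unchanged genes varied by counting error only. Of 50 genes made 2-fold different, 46 were recovered for IKVAV PA against PDL, 45 for IKVAV PA + PEDOT-S against PDL and 46 between the scaffolds. At 1.75-fold 41, 41 and 38 of 50 were recovered, and at 3-fold and 4-fold all 50 in each. None of 13684 unchanged genes was counted, and the intervals covered the true ratio for 95.3%, 95.3% and 95.7% of all 13884 genes. Without variation between cultures in the simulation, these figures check the calculation and say nothing of false calls in the real libraries. Of 100 simulated lists without a shift, 94, 95 and 93 lay inside the random lists, and 100 of 100 lists of 20 genes with a log2 shift of 0.15 lay outside. These lists were drawn at random from genes that varied by counting error only. They too check the calculation alone and do not give the power for lists in the real libraries.

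Alternatives were DESeq2 1.42.0 size factors, total counts without factors, other expression filters, a 2-fold bound, libraries thinned to the smallest total, an assumed biological variation, protein-coding genes alone, another prior count, means in place of medians, and random lists matched in other ways. Chosen after seeing the data were leaving out genes with shared exons, removing a trend on exonic length and GC content, and thinning for lists. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.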

Results

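RNA-seq gene counts were analysed from 3 libraries of cultured wildtype CD1 mouse cortical neurons, 1 library per group. The IKVAV PA library came from neurons on a peptide amphiphile, a self-assembling peptide material, which carried IKVAV, a short sequence from the matrix protein laminin. The IKVAV PA + PEDOT-S library came from the same kind of scaffold with a further component taken to be PEDOT-S, a sulfonated conducting polymer. Its title calls this component PS2 and its library name PEDOT-S_OH, and that both are the same material is an assumption. The library labelled PDL served as the control, and the labels do not spell PDL out. The series concerns whether conductive and bioactive scaffolds promote the maturation of neurons, so the design implies 3 comparisons, each scaffold against the PDL control and the 2 scaffolds against each other. Groups were taken from the sample titles and library names, because the treatment field reads the same for all 3 libraries, the control included. Total counts were 124425958 for IKVAV PA, 79057998 for IKVAV PA + PEDOT-S and 78993105 for the PDL control, and 29909, 26436 and 27630 genes had at least 1 count. All 3 libraries are repeat 3 of their group, and repeats with other numbers were not analysed here, so every difference below has no replicate check. No test between groups was possible, the differences describe these libraries and not the conditions, and all intervals cover counting error only.

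Most cell cycle and astrocyte markers and many matrix genes were lower in the IKVAV PA library than in the PDL control library, while a few myelin genes were higher and neuronal genes lay close together. Mki67, the proliferation marker, stood at 12.7 normalised CPM (counts scaled to library size) against 42.1, which was 3.32-fold lower (log2 ratio -1.73, 95% counting interval -1.82 to -1.65). Fabp7, a lipid-binding protein of radial glia and astrocytes, was 3.78-fold lower (29.5 against 112 CPM), and Lox, which cross-links collagen, was 4.28-fold lower (log2 ratio -2.10, interval -2.28 to -1.92). Olig1, a transcription factor of the oligodendrocyte lineage, was 3.77-fold lower (7.04 against 26.6 CPM). By contrast Map2, a dendritic microtubule protein, had a log2 ratio of 0.00, and Dcx, a microtubule protein of young neurons, one of 0.06.

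Of 13884 genes compared, 75 were higher and 475 lower in the IKVAV PA library by more than 1.5-fold beyond counting error, and 96.0% lay within that bound. The lowest named genes also included Gna14, a G protein alpha subunit (-2.95, from 17 against 84 counts), Ctsc, the lysosomal protease cathepsin C (-2.57), Akr1c14 (-2.37), Ttyh2 (-2.29), Slfn9 (-2.06), Emp1 (interval -2.20 to -1.81) and Kcnj10, a potassium channel of astrocytes (-1.91). The highest genes included Mal, a proteolipid of myelin (2.13, at 0.714 against 0.163 CPM), Adnp (1.82), Pla2g3 (1.39), Rab43 (1.38), Snx22 (1.28), Gnas (1.24), Phyhd1 (1.19), Scand1 (1.11) and Glcci1 (1.08). In all of these but Mal and Pla2g3, over 10% of the exonic bases are shared with another gene, as against 13.4% of all genes compared, so their values are uncertain. Of the 75 higher genes, 44 were not protein-coding, against 7 of the 475 lower genes.

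Among the cell cycle genes, 16 of 20 were lower in the IKVAV PA library, none was higher, and the median log2 ratio of -1.30 lay below all 10000 random lists matched on expression. Ccnb1, the mitotic cyclin B1, was at -1.75, and Pcna, a replication clamp also used in DNA repair, at -0.29. Neural progenitor markers had a median of -0.69, also below all random lists, with 6 of 12 lower, among them Nes, the intermediate filament nestin (-1.57). Astrocyte markers had a median of -0.73, below all random lists, with 11 of 18 lower, such as Aldh1l1, an enzyme of folate metabolism with 13.4% of its exonic bases shared (-1.85). Gfap, the astrocyte filament protein, was weakly expressed at 0.497 against 0.402 CPM (0.31, interval -0.33 to 0.97). Meningeal fibroblast markers (6 of 12 lower, median -0.85) lay below all random lists, and endothelial and pericyte markers (4 of 8 lower, median -0.71) lay at the 0.530 percentile. The oligodendrocyte lineage list was split. Its median was -0.42 (percentile 0.1) with 6 of 15 lower, among them Olig1 and Olig2 (-1.85), and 2 higher, the myelin genes Mag (1.13) and Mobp (1.01), of which Mobp no longer passed the bound with the libraries thinned to 1 total. Of 20 microglia and macrophage markers only 3 passed the expression filter, and none of 9 erythroid genes did.

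Matrix genes were lower as well, 14 of 25, with a median of -0.71 below all random lists. Sparc, a collagen-binding matrix protein, was 2.85-fold lower and the laminin chain Lamb2 was at -1.65, whereas the proteoglycan Vcan was at 0.17. The list of YAP and SRF targets and actin cytoskeleton genes had a median of -0.98, below all random lists, with 9 of 18 lower, such as Acta2, smooth muscle actin (-1.57), and Ajuba (-1.90). Of 22 integrins and other laminin-binding or adhesion genes 3 were lower and none higher (median -0.26, below all random lists). They were Itga5 (-1.50), Itgb5 (-1.22) and Itgav (-0.86), the last named after its value was seen. Itgb1, the beta subunit shared by many laminin receptors, was at -0.54 (interval -0.58 to -0.49).

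No member of the pan-neuronal, maturation, presynaptic, postsynaptic, glutamate receptor or ion channel lists passed the 1.5-fold bound in this comparison. The scaling puts the median ratio of all genes near no difference. In cultures of neurons, list medians near no difference therefore cannot show that neuronal RNA as a whole was unchanged. The pan-neuronal median was -0.01 (percentile 19.6), the maturation median -0.04 (percentile 6.15) and the presynaptic median 0.00 (percentile 31.8, with a mean of opposite sign), all inside the middle 95% of random lists. Rbfox3, the neuronal nuclear protein NeuN, was at 0.22, Syn1, a synaptic vesicle protein, at 0.02, and Dlg4, the postsynaptic scaffold PSD-95, at -0.08. Slc17a7, a vesicular glutamate transporter, was at 0.20 and Gad1, a GABA-synthesising enzyme, at -0.23. Small shifts of whole lists were present. The excitatory neuron list was at 0.12 (percentile 99.99), the sodium and calcium channel list at 0.15 (above all random lists), the GABA-A receptor list at -0.14 (below all random lists), and the inhibitory interneuron list at -0.07 (percentile 1.06). The postsynaptic list was at 0.08 (percentile 99.6), but inside the random lists once a trend on gene length and GC content was removed.

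The early and late lists of activity-dependent genes had lower medians in the IKVAV PA library. Some members also stand in other lists, such as Btg2 among the p53 targets and Ptgs2 among the NF-kB and inflammatory genes. Neuronal activity itself was not measured, so these lists cannot show a difference in it. Of 22 early activity-dependent genes 19 had a negative ratio and the median was -0.33, and all 20 late genes were negative with a median of -0.43. Both medians lay below all 10000 random lists. Few members passed the 1.5-fold bound. They were Btg2 (-0.93) among the early genes, and Bdnf, a neurotrophin (-0.80, 26.8 against 46.6 CPM), Nptx2, a synaptic pentraxin (-0.89), and Scg2, a secretogranin (-0.63), among the late genes. Fos, the immediate early transcription factor, was at -0.63 (interval -0.69 to -0.57). The cholesterol synthesis list was at 0.02 (percentile 66.1), with no member past the bound.

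Against the same PDL control, the IKVAV PA + PEDOT-S library also had lower levels of dividing-cell, matrix and contractile genes. A few myelin genes were higher, as in the IKVAV PA library, and sterol synthesis genes were higher as a list, with 3 of 24 past the bound. Col1a1, the main chain of type I collagen, was 6.23-fold lower (5.61 against 35.0 CPM, log2 ratio -2.64, interval -2.79 to -2.49), and Acta2 was 7.86-fold lower (9.99 against 78.5 CPM). Mki67 was 3.33-fold lower. Mobp and Mag, proteins of the myelin sheath, were 4.84-fold and 4.08-fold higher, though only at about the level of weakly expressed genes (4.13 and 4.10 CPM). Stard4, a sterol transfer protein, was 1.66-fold higher (207 against 125 CPM).

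In this comparison 62 of 13884 genes were higher and 522 lower by the same rule, and 95.8% lay within the bound. The lowest genes included Spp1, osteopontin (-3.38, with 18.8% of its exonic bases shared), Lox (-3.37), Lrrk1 (-3.34), Acta2 (-2.97), Cd44, a hyaluronan receptor (-2.92), Lgals1, galectin-1 (-2.77), Vcam1, an adhesion molecule (-2.73), Abca1, a cholesterol exporter (-2.68), and Col1a1. The highest included Mal (3.23, at 1.53 against 0.163 CPM), Mobp (2.27), Mag (2.03), Adnp (1.98), Gfap (1.79), Nxph4 (1.68), Scand1 (1.49), Gnas (1.37) and Glcci1 (1.27). Adnp, Scand1, Gnas and Glcci1 share over 10% of their exonic bases with other genes and are uncertain. Without all such genes, a choice made after seeing the data, 41 higher genes were counted.

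Of the cell cycle genes 15 of 20 were lower, with a median of -1.45 and Ccnb1 at -2.07. Progenitor markers had a median of -0.68 (5 of 12 lower), including Nes (-1.36), while Eomes, a factor of intermediate progenitors, was at 0.69 without passing the bound. Matrix genes had a median of -0.998 (17 of 25 lower), the YAP, SRF and actin list one of -1.63 (10 of 18 lower), and meningeal fibroblast markers one of -1.43 (9 of 12 lower). Each of these 5 medians lay below all random lists, and the endothelial and pericyte median of -1.37 (6 of 8 lower) lay at the 0.0100 percentile. Sparc was at -2.34, Itga5 at -2.28 and Cspg4, a proteoglycan of pericytes and oligodendrocyte precursors, at -2.67. Integrins and laminin-binding genes had a median of -0.23, below all random lists, with 6 of 22 lower. Astrocyte markers were lower in 5 of 18 and higher in 1, with a median of -0.39 below all random lists. The 1 higher gene was Gfap, at 109 against 32 counts, while Aldh1l1 was at -1.41.

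The oligodendrocyte lineage list went both ways, with a median of -0.02 (percentile 79.8) and 6 of 15 members within the bound. The 5 higher members included Mobp, Mag, Myrf (1.13), which drives myelin genes, and Mbp (0.91), a main myelin protein. The 4 lower members were Cspg4 and Pdgfra (-2.56), which are also in the pericyte and fibroblast lists, and Olig1 (-1.97) and Olig2 (-1.84). Mbp was named after its value was seen. All 24 measured cholesterol synthesis and SREBP target genes had a positive ratio, with a median of 0.40 above all random lists, although only 3 passed the bound. These were Mvd (0.75) and Mvk (0.75, named after its value was seen), both enzymes of the mevalonate pathway, and Stard4 (0.73). LXR target and lipid handling genes were lower in 5 of 12 (median -0.22, percentile 0.25), with Abca1 lowest. In IKVAV PA against PDL 4 of 12 were lower as well, with the median inside the random lists (-0.06, percentile 13). Between the scaffolds 2 were lower, and that median also lay inside (-0.04, percentile 26.5).

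Neuronal lists again lay close to 0, with the same limit from the scaling. The pan-neuronal median was 0.04 (percentile 66.0), while the maturation median of -0.05 (percentile 1.11) and the presynaptic median of -0.02 (percentile 0.870) lay just below the middle 95% of random lists. Both lay inside random lists that were not matched on expression. Camk2a, a synaptic kinase that increases as neurons mature, was at -0.50, Syn1 at -0.16, Dlg4 at -0.14, Gad1 at -0.33, Map2 at -0.04 and Rbfox3 at 0.17. The excitatory neuron list was at 0.17 (percentile 99.99) with no member past the bound, and Tle4, a deep-layer marker, was at 0.51. The list of immature neuron and axon growth genes was at 0.13 (percentile 99.8), with Sox4, 54.6% of whose exonic bases are shared, past the bound (0.67). That list lay inside the random lists with the length and GC trend removed. The early activity list was at 0.08 (percentile 98.8) and the late list at -0.05 (percentile 7.39), and no member of either passed the bound. The early median turned slightly negative once the length and GC trend was removed. Fos was at -0.24 and Bdnf at -0.29.

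**Figure D1:**
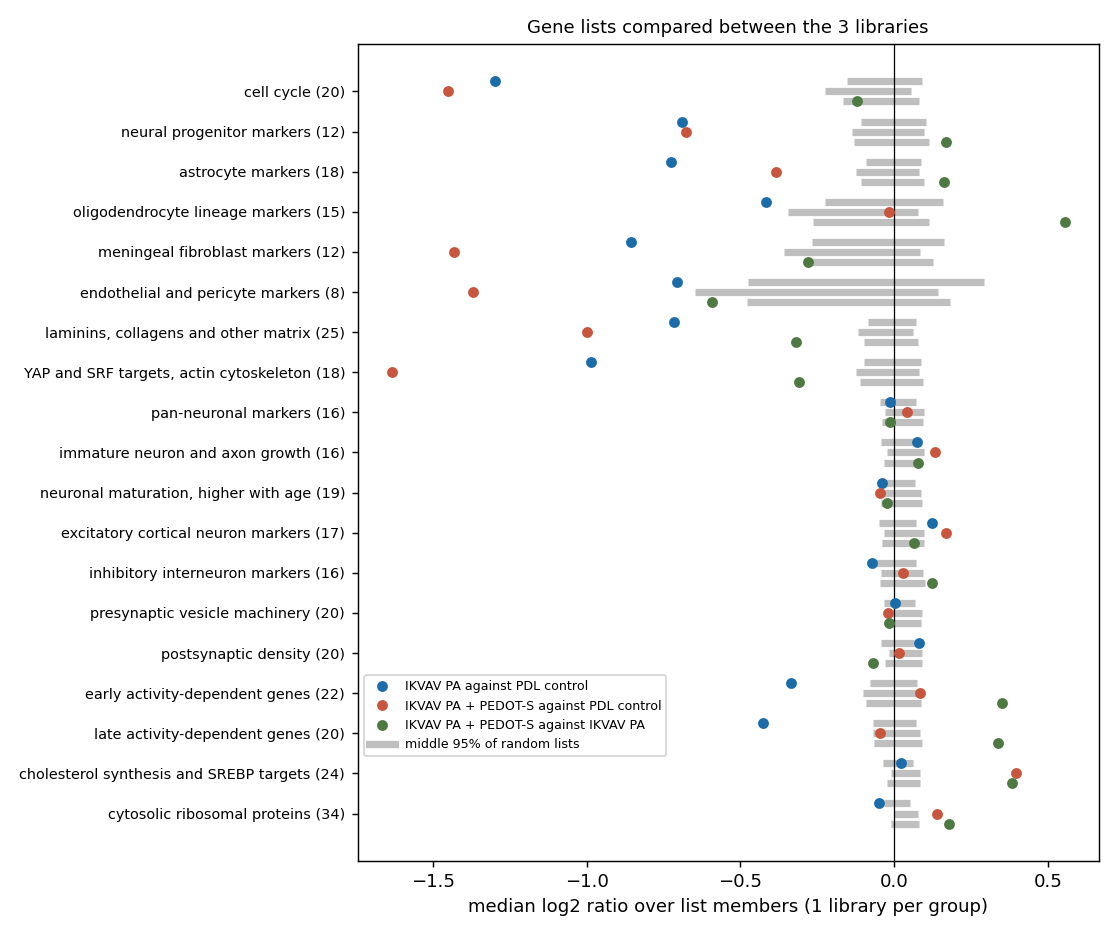
Median log2 ratio (horizontal axis) of 19 fixed gene lists, with the number of measured members in parentheses, for the 3 comparisons (coloured points, 1 library per group). Grey bars are the middle 95% of random lists matched on expression, and the cell cycle points against PDL lie at -1.30 and -1.45, left of theirs, while the pan-neuronal points lie inside theirs.

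Between the 2 scaffolds, the lists of activity-induced and sterol synthesis genes had higher medians in the IKVAV PA + PEDOT-S library than in the IKVAV PA library, though few of their members passed the 1.5-fold bound. Some weakly expressed myelin genes were higher, and matrix and contractile genes had lower medians. Nptx2 was 1.98-fold higher (20.2 against 10.2 CPM, log2 ratio 0.98, interval 0.87 to 1.09), Stard4 was 1.65-fold higher (207 against 126 CPM) and Mobp was 2.40-fold higher (4.13 against 1.72 CPM). Col1a1 was 2.59-fold lower (5.61 against 14.5 CPM) and Abca1 3.12-fold lower (3.35 against 10.5 CPM). Mki67 stood at 12.7 CPM in both libraries.

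By the same rule 46 of 13884 genes were higher and 279 lower with PEDOT-S, and 97.7% lay within the bound. Of the 279 lower genes 136 were not protein-coding, against 4 of the 46 higher genes. The lowest genes included Spp1 (-2.55), Crip3 (-1.79), Lrrk1 (-1.74), Abca1 (-1.64), Adamts12, a matrix protease (-1.58), Rtbdn (-1.50), Kcnq1ot1, a long nuclear RNA (-1.44), Acta2 (-1.40) and Col1a1 (-1.37). The highest were Ttr, transthyretin (1.65), Myrf (1.56), Layn (1.52), Hist1h4h (1.52), Gfap (1.49), Ptgs2, an inducible cyclooxygenase (1.49), Mobp (1.27), Aldoc (1.24), Hist1h2bc (1.20) and Slc7a3 (1.11). None of these 10 shares over 10% of its exonic bases with another gene.

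The early activity median was 0.35, with 20 of 22 members positive, and the late activity median was 0.34, with 17 of 20 positive. Both lay above all random lists, but only Nptx2 and Ptgs2, which is also in the NF-kB and inflammatory list, passed the bound. Egr2, an early growth response factor, was at 0.88, Bdnf at 0.51 and Fos at 0.39. All 24 sterol synthesis genes were positive (median 0.38, above all random lists), with Stard4 (0.72) past the bound and Insig1, a sterol sensor, at 0.61. Oligodendrocyte lineage markers were higher in 7 of 15 and lower in 2, with a median of 0.55 above all random lists. That median turned slightly negative when only genes at 5 CPM or more were kept. Astrocyte markers were higher in 3 of 18, among them Gfap and Aldoc, with a median of 0.16 (percentile 99.95). Progenitor markers were at 0.17 (percentile 99.8) and cell cycle genes at -0.12 (percentile 9.80), with none past the bound in either list.

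Matrix genes were lower in 5 of 25 (median -0.32) and YAP, SRF and actin genes in 5 of 18 (median -0.31), both below all random lists. Meningeal fibroblast markers were lower in 2 of 12 (median -0.28, percentile 2.31), though inside random lists also matched on length, and endothelial and pericyte markers in 3 of 8 (median -0.59, percentile 0.900). Integrins and laminin-binding genes were at -0.05 (percentile 9.16), and Itgb1 was at 0.05. Of neuronal lists, sodium and calcium channels were at -0.16, below all random lists, with 21 of 24 negative, and the postsynaptic list was at -0.07 (percentile 0.0800). Inhibitory interneuron markers were at 0.12 (percentile 99.5), including Sst, somatostatin (0.46). No member of these 3 lists passed the bound. The pan-neuronal (-0.01), maturation (-0.02), presynaptic (-0.02) and glutamate receptor (0.02) medians lay inside the middle 95% of random lists, and the pan-neuronal and glutamate receptor means had the opposite sign. Slc17a7 was at -0.25 and Slc12a5, the potassium-chloride transporter of mature neurons, at -0.48.

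Of the other lists, reactive astrocyte genes were lower in 4 of 9 in IKVAV PA against PDL (median -0.42, percentile 0.635) and lower in 4 and higher in 1 of 9 in IKVAV PA + PEDOT-S (median -0.43, percentile 2.10), and had a median of 0.06 between the scaffolds. Neurotrophic signalling genes were at -0.11 in IKVAV PA against PDL (percentile 0.16, 2 of 16 lower), and at -0.07 and 0.05 in the other 2 comparisons, inside the random lists. Glycolysis and hypoxia genes were at -0.09 and -0.06 against PDL (percentiles 0.02 and 0.34) and at 0.09 between the scaffolds (percentile 98.9), where Hk2, a hexokinase, was at 0.77. Nuclear genes of oxidative phosphorylation were at -0.07, 0.04 and 0.10 in the same order, with percentiles of 0.15, 67.7 and 99.4. The 15 housekeeping genes were at -0.07, -0.08 and 0.10 (percentiles 1.82, 1.25 and 97.7), with Actb, beta actin, at -0.07, 0.02 and 0.09, so shifts of this size were not limited to special groups of genes. Potassium channels (0.05, -0.02 and -0.02), axon guidance genes (-0.02, 0.02 and 0.05), choroid plexus and ependymal markers (-0.40, -0.51 and -0.16) and metal response genes (-0.02, -0.06 and 0.01) lay inside the random lists in all 3 comparisons. The means of the potassium channel and axon guidance lists had the opposite sign to their medians in IKVAV PA + PEDOT-S against PDL.

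Some genes lay apart from both neighbours in the IKVAV PA library. They were counted by the 1.5-fold rule among the 12279 genes open to naming, without numbered gene models, pseudogenes, mitochondrial and antisense genes. Of these, 14 were lower in IKVAV PA than in PDL and higher again with PEDOT-S, and 12 were higher and then lower. The 2 numbers do not describe all 13884 genes, since many genes higher in IKVAV PA were not protein-coding. The first set included Aldoc, a glycolytic enzyme of astrocytes (-1.86, then 1.24), Ttr (-1.11, then 1.65) and Nptx2 (-0.89, then 0.98). The second included Rtl1, an imprinted gene (1.04, then -1.38), and Rn7sk, a small nuclear RNA (1.02, then -1.01).

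**Figure D2:**
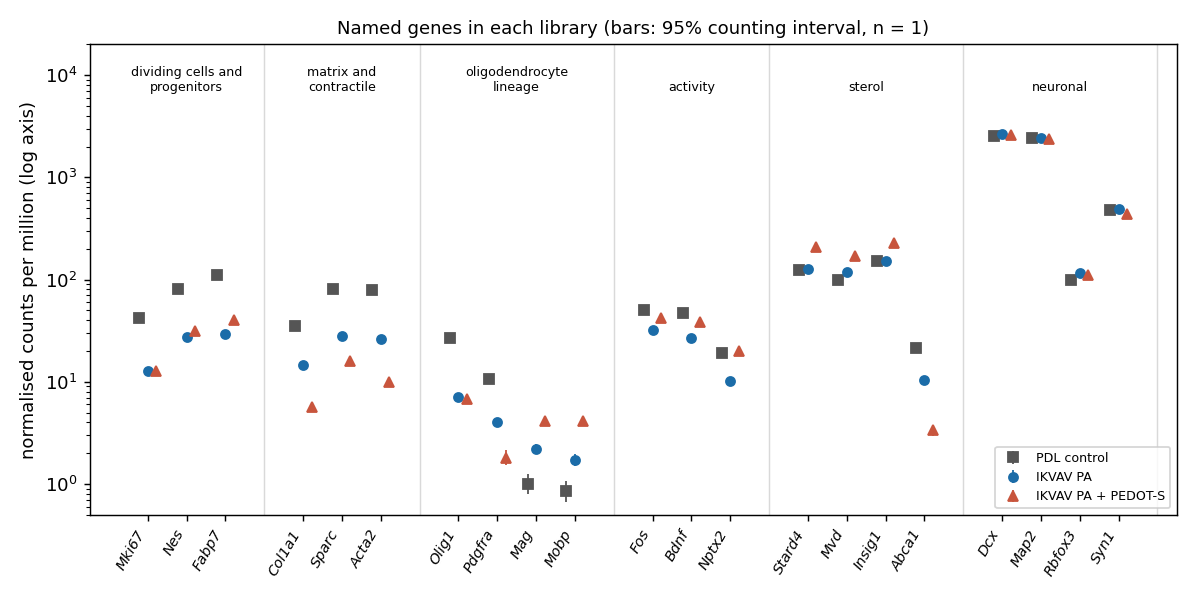
Normalised CPM (vertical log axis) of named genes in the PDL control (squares), IKVAV PA (circles) and IKVAV PA + PEDOT-S (triangles) libraries, 1 library each, with 95% counting intervals as bars. Mki67 stands at 42.1 in the PDL control and 12.7 in both scaffolds, Col1a1 at 35.0, 14.5 and 5.61, and the neuronal genes lie nearly level.

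The 2 scaffold libraries lay closest to each other, with a standard deviation of log2 ratios of 0.293 across genes, against 0.336 for IKVAV PA and 0.381 for IKVAV PA + PEDOT-S against the PDL control. Simulated counting error alone gave 0.0888, 0.0843 and 0.0957. Spearman's rho across genes, which are not independent replicates, was 0.996, 0.994 and 0.993. The genes lower than in the PDL control overlapped, with 372 lower in both scaffold libraries. Independent lists would share 17.9, and libraries simulated with a common control shared 19.4. In these simulations no gene differed by group, but each library had added variation between genes as large as that seen between the 2 scaffold libraries at the same expression. Of higher genes 17 were shared, against 0.335 and 15.4, and 3 genes went in opposite directions. The correlation of log2 ratios across genes was 0.674, against 0.505 simulated, with a covariance of 0.0862 against 0.0394. The simulated control varied no more than a scaffold library, so the simulation does not cover an unusual PDL culture. With 1 control library no split of the control was possible, so part or all of the excess may come from that library.

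The main named genes are protein-coding and lie, in the GRCm38 (mm10) assembly, as follows. Mki67 (ENSMUSG00000031004) spans 135689784 to 135716361 on chromosome 7, and Mag (ENSMUSG00000036634) spans 30899176 to 30914873 on the same chromosome. Col1a1 (ENSMUSG00000001506) spans 94936224 to 94953042 on chromosome 11, and Acta2 (ENSMUSG00000035783) spans 34241090 to 34255590 on chromosome 19. Mobp (ENSMUSG00000032517) spans 120149707 to 120181484 on chromosome 9. Nptx2 (ENSMUSG00000059991) spans 144545902 to 144557478 on chromosome 5, Stard4 (ENSMUSG00000024378) spans 33199355 to 33213862 on chromosome 18, and Bdnf (ENSMUSG00000048482) spans 109674700 to 109727007 on chromosome 2. Of these, Bdnf shares 14.4% of its exonic bases with another gene, so its counts are uncertain.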

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

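Leaving out genes with shared exons, removing the length and GC trend, and thinning for lists were chosen after the results were seen. No paired analysis was possible because each group has 1 library and no test was made. Of the list results under alternatives, 1078 kept their place inside or outside the random lists, 33 moved outside, 39 moved inside and 2 reversed. Direction was checked only for lists outside the random lists in the main setting. Lists that stayed inside could therefore change sign and still be among the 1078. Named genes were rerun only with DESeq2 size factors, total counts and thinned libraries, which alter ratios little. Of these results, 1666 were the same, 4 passed the 1.5-fold bound newly and 4 no longer did. DESeq2 size factors and total counts moved the median log2 ratio of all genes by -0.0268 at most.

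Gene counts, as higher and lower, depended on the filter and bound. They are given for IKVAV PA against PDL, IKVAV PA + PEDOT-S against PDL and the 2 scaffolds, in that order. Without a filter they were 484 and 846, 247 and 1074, and 230 and 1122, so that 63.6% of the first were lower, against 86.4% with the filter. At 5 CPM or more they were 18 and 227, 37 and 232, and 23 and 96, because fewer genes were compared. At a 2-fold bound they were 9 and 219, 13 and 257, and 7 and 75. With an assumed biological coefficient of variation of 0.2, which was not measured here, they were 9 and 150, 11 and 216, and 3 and 52. Among protein-coding genes alone, 31 were higher in IKVAV PA than in PDL and 143 lower with PEDOT-S than in IKVAV PA. With shared-exon genes left out, 41 were higher in IKVAV PA + PEDOT-S than in PDL.

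For the similarity of the 3 libraries: SD of log2 ratios, IKVAV PA against PDL control was 0.244 at 5 CPM or more, with 0.289 and 0.205 for the other pairs. At the 2-fold bound 6 genes were higher and 170 lower in both scaffolds than in PDL, and 0 went in opposite directions. The median log2 ratio of early activity-dependent genes, IKVAV PA + PEDOT-S against PDL control, was -0.00077 (main value 0.08) with the length and GC trend removed, and the cause was not tested. The median log2 ratio of oligodendrocyte lineage markers, IKVAV PA + PEDOT-S against IKVAV PA, was -0.025 (main value 0.55) at 5 CPM or more, where most weakly expressed myelin genes were left out by construction. With libraries thinned to 78993105 counts, 28795, 26435 and 27630 genes had a count in IKVAV PA, IKVAV PA + PEDOT-S and PDL, so depth gave part of the greater number of genes detected in IKVAV PA.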

Other observations

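The tests of equal loss of non-neuronal cells, of unspliced material and of astrocytes as a source were chosen after the results were seen. The medians of the ribosomal protein and some stress lists were shifted slightly between the scaffold libraries, with almost no member past the 1.5-fold bound. All 34 measured cytosolic ribosomal protein genes had a positive ratio in IKVAV PA + PEDOT-S against IKVAV PA. Their median of 0.18 lay above all random lists, with none past the 1.5-fold bound. With PEDOT-S 33 of 34 were positive against PDL (median 0.14), while in IKVAV PA against PDL 27 of 34 were negative (median -0.05, percentile 0.2). The unfolded protein and amino acid response list was at 0.18 between the scaffolds, above all random lists, with 21 of 24 positive, such as Cebpb, a stress-induced transcription factor with 20.7% of its exonic bases shared (0.78), and Chac1, a glutathione-degrading enzyme (0.65). The NRF2 list was at 0.14 (percentile 99.98). Both differences sat in a low IKVAV PA library, since against PDL these lists were at -0.13 (percentile 0.01) and -0.13 (below all random lists) in IKVAV PA and inside the random lists, at 0.04 and -0.01, with PEDOT-S. The p53 target list was at 0.15 between the scaffolds (percentile 99.93) and at 0.16 with PEDOT-S against PDL (percentile 99.99). Mitochondrially encoded mRNAs, of which 7 of 13 listed passed the filter, went the other way between the scaffolds. Their median was -0.23 with 7 of 7 negative, below all random lists, but inside them with the length and GC trend removed. Without that removal, their median against PDL was -0.28 with PEDOT-S, below all random lists, and -0.07 in IKVAV PA (percentile 0.92). Heat shock genes lay inside the random lists between the scaffolds but were at -0.15 in IKVAV PA against PDL (percentile 0.0400), where all 15 were negative and 3 passed the bound, among them the small chaperone Hspb8 (-2.02).

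Of 4 measured replication-dependent histone genes, 3 were higher with PEDOT-S than in IKVAV PA (median 1.08), including Hist1h4h (1.52) and Hist1h2bc (1.20). Interferon genes (6 measured) and NF-kB and inflammatory genes (9 measured) lay inside the random lists in all 3 comparisons, with medians of -0.18, -0.27 and -0.02 and of -0.17, -0.14 and -0.05. Between the scaffolds the means of the NF-kB, heat shock and microglia lists had the opposite sign to their medians. Among the sex-linked genes Xist stood at 742, 608 and 621 CPM in IKVAV PA, IKVAV PA + PEDOT-S and PDL, and Y-linked genes were present in every library. In IKVAV PA against PDL, 26.7% of higher genes shared over 10% of their exonic bases with another gene, against 8.42% of lower genes. In IKVAV PA + PEDOT-S against PDL these shares were 33.9% and 8.24%, and between the scaffolds 8.70% and 14.0%. The excess among higher genes was thus seen in both comparisons with the PDL library and not between the scaffolds. No explanation of this was tested.

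The cell cycle, progenitor, astrocyte, meningeal fibroblast, endothelial and pericyte, and matrix lists had lower medians in both scaffold libraries than in the PDL library, while the oligodendrocyte list did so outside the random lists in IKVAV PA alone and choroid plexus and microglia lists lay inside them. A fitted trend on gene length and GC content explained 1.74% of the variance of log2 ratios (large ones capped) in IKVAV PA against PDL. In IKVAV PA + PEDOT-S against PDL it explained 3.15%. The trend as fitted thus accounts for little of the pattern. The cell cycle median stayed at -1.28 in IKVAV PA and -1.44 in IKVAV PA + PEDOT-S after its removal, but so weak a trend could hardly have moved it. In IKVAV PA + PEDOT-S the astrocyte median lay above the meningeal fibroblast median by 1.05 (95% bootstrap interval over members 0.32 to 1.29). In IKVAV PA the difference was 0.13 (interval -0.55 to 0.93). These intervals cover the choice of list members only, with 1 library per group. Lists whose members are expressed to different degrees in the remaining cells would also differ in median under an equal loss. Whether all non-neuronal cells were lost equally therefore cannot be decided from these differences in either scaffold library. Fewer dividing cells on the scaffolds, or a PDL culture with unusually many, may each account for the pattern, and 1 library per group does not separate them.

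Provisional (TEC), antisense, sense-intronic and lincRNA gene models had higher medians in the IKVAV PA library than in the other 2, while 344 processed pseudogenes did not (-0.02 against PDL). The IKVAV PA + PEDOT-S library departed from PDL the other way, at -0.21 for TEC (144 of 190 negative) and -0.14 for antisense models (128 of 200 negative). Its lincRNA and sense-intronic medians against PDL were closer, at -0.05 and -0.02. The 190 gene models of the provisional class TEC, of which 39.5% lie inside a protein-coding gene on its strand, had medians of 0.29 against PDL and 0.52 against IKVAV PA + PEDOT-S, and Meg3, an imprinted nuclear RNA chosen after its values were seen, stood at 1897, 920 and 1261 CPM in IKVAV PA, IKVAV PA + PEDOT-S and PDL. Against IKVAV PA + PEDOT-S the median was 0.514 with the libraries thinned to a common total, but thinning hardly alters ratios of scaled counts, so this does not decide on sequencing depth. More unspliced, nuclear or genomic material cannot be told apart from a biological difference between the cultures, because the TEC medians, the lower being 0.288, are the pattern itself and not a test of it. Rian, another such RNA, was nearly level at 541, 519 and 530 CPM.

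The lists of activity-induced and sterol synthesis genes had higher medians with PEDOT-S than in IKVAV PA. A fitted length and GC trend explained 3.42% of the variance of log2 ratios between the scaffolds and thus accounts for little of this. With it removed, the medians were 0.35 for early activity genes, 0.34 for late activity genes and 0.39 for sterol synthesis genes. All lay above all random lists, but so weak a trend could move them little. More astrocytes as a source of the sterol genes stays open, since the astrocyte median was -0.39 (interval -0.72 to -0.24) in IKVAV PA + PEDOT-S against PDL but 0.16 (percentile 99.95, interval -0.03 to 0.44, 11 of 18 positive) between the scaffolds. The activity genes were low in IKVAV PA rather than high with PEDOT-S relative to PDL, at -0.33 and -0.43 against 0.08 and -0.05. TEC models were highest in the same IKVAV PA library, a link that was not tested. The sterol genes instead stood apart in the IKVAV PA + PEDOT-S library, at 0.40 against 0.02. An effect of the scaffold, of handling or of a single unusual culture may each give these values, and 1 library per group does not separate them.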
